A study of Homo sapiens with 4 samples.

How the data were processed

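RNA was measured in 4 libraries of MDA-MB-231 cells, 1 each for vector cells in DMSO, ARL11 cells in DMSO, vector cells in olaparib and ARL11 cells in olaparib. Per the labels' protocols, 500000 cells were plated on 10 cm dishes in medium with 10% serum and cultured for 24 hours before the 3 days of treatment. RNA was extracted with a phenol reagent and made into strand-specific libraries for Illumina sequencing with a NEBNext kit. How ribosomal RNA was avoided and how many dishes went into a library are not given in the sources used here. Per the submitters' processing notes, FastQC, STAR, SAMtools and featureCounts were used with the build GRCh38, in versions not given in the sources used here.

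The deposited values are CPM, read counts scaled to library size, for 25611 genes in each library, per the file headers and the values. Within each library the deposited CPM were whole multiples of the value of 1 read for 100% of genes at a tolerance of 0.01 reads, so whole reads were recovered. One read was worth 0.134, 0.122, 0.148 and 0.161 CPM in the libraries in the order above, and the reads summed to 7472981, 8112702, 6878212 and 6171087. The ratios of effective to listed totals, 1.00007, 1.01, 0.984 and 1.01, equalled the TMM factors that edgeR computed from the recovered reads. Genes with at least 1 read numbered 20497, 20806, 20252 and 20116. A floor of 3 reads lay at 0.401, 0.366, 0.443 and 0.483 CPM.

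The 12000 genes with the highest mean CPM over the libraries were used. Their lowest mean was 2.78 CPM, their lowest sum 74 reads over the 4 libraries, and they held 99.4% of the reads. Values were transformed as log2 of CPM plus a pseudocount of 1. Each of 4 contrasts was a difference of 2 libraries, namely olaparib against DMSO in either line and ARL11 against vector in either treatment. The difference of responses was that of ARL11 cells minus that of vector cells. With 1 library per group these contrasts have no test, and genes were counted by a fixed size, at least 2-fold. Counting errors of a difference are by the delta method on the scale of log2 CPM plus 1. Folds of single genes are ratios of CPM with exact Clopper-Pearson intervals at 95% from the recovered reads.

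An additive model of line and treatment was fitted over all 4 libraries with limma 3.58.1, with a trended prior variance and Benjamini-Hochberg adjustment at 0.05. It leaves 1 residual degree of freedom per gene, which is the departure from additivity, beside 12.3 prior degrees of freedom, so its p-values measure that spread only. The words rose and fell refer to this test. Count tests on the recovered reads in the same model were run as alternatives. edgeR 4.0.16 (quasi-likelihood) called 3594 genes higher and 4278 lower with olaparib, and DESeq2 1.42.0 called 2685 and 3049. Limma shared 3589 and 4274 of its calls with edgeR. The fits were tested on simulated counts drawn for the 12000 genes, with known changes for olaparib. Limma called 83 of 100 genes changed 2-fold, 98 of 100 changed 4-fold and 6 of 11800 unchanged genes, and edgeR called 84, 98 and 10. The simulation assumed the same small dispersion for every gene and independent libraries. It held no difference in response between the lines and no length or GC trend, and most genes were unchanged. These rates therefore do not carry over to the real libraries.

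A total of 38 gene lists with 1065 distinct genes were fixed before the data were examined, as were the designs, the size rule and most of the other settings tried. They cover DNA repair, the cell cycle, innate immunity, stress, metabolism and markers of other cell types. For the 34 lists with at least 5 members among the 12000 genes, the median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart under 2.5 or over 97.5. Percentiles describe these libraries only.

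Genes named in the text follow a rule fixed at the same time. It takes ARL11, PARP1 and PARP2. For olaparib and for ARL11 it takes the 10 genes each way with the largest smaller ratio of the same sign in both contrasts, passing over clone and locus names. For the difference it takes the 5 highest and the 5 lowest. From a list it takes up to 4 members, the highest and the lowest by the mean ratio. Members of lists cited for a single contrast come from these. Some genes that the rule names are not reported here.

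Transcript length (median over a gene's basic transcripts), GC content (of the longest) and gene span came from GENCODE release 29 on GRCh38, matched by identifier for 97.7% of all genes and 11990 of the 12000. The release behind the deposited values is not given in the sources used here. The other settings fixed beforehand were pseudocounts of 5 and 0.1, the 8000 genes of highest mean, no filter on low values, rescaling to the median ratio, the upper quartile or the same total, limma with a constant prior, the count tests and random lists without matching. After the data were seen, removal of a smooth trend in length and GC content was added, with a spline of 5 knots per variable fitted to each library, as was the same with the longest transcript, and partial rank correlations. The removal keeps each library's mean over genes, not its median. Counting error was simulated 100 times with Poisson counts, which hold none of the spread between dishes and libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and R 4.3.3 were used.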

Results

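Gene expression was measured by RNA sequencing in MDA-MB-231, an established human cell line of triple-negative breast cancer, carrying either an empty vector or an overexpressed ARL11. ARL11 is a small GTPase of the ADP-ribosylation factor-like family. Each line was kept for 3 days with olaparib, an inhibitor of the poly(ADP-ribose) polymerases PARP1 and PARP2, or with its solvent DMSO. The labels give 40 µM for both treatments. The 4 groups held 1 library each, so no difference between 2 libraries has a replicate check, and values compare these libraries. Total reads in genes were 7472981 for vector cells in DMSO, 8112702 for ARL11 cells in DMSO, 6878212 for vector cells in olaparib and 6171087 for ARL11 cells in olaparib. Log2 ratios are of CPM plus 1, which understates the change of low genes. Folds are ratios of CPM, with 95% exact intervals that cover counting error only.

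The overexpressed gene was examined in each library before the comparisons. ARL11 (ENSG00000152213.4, chromosome 13, 49628299 to 49633872 on the plus strand of GRCh38, 2 exons, protein coding) was at 0 CPM in vector cells in DMSO and at 123 CPM, 1008 reads, in ARL11 cells in DMSO. In olaparib it was at 0.443 CPM, 3 reads, in vector cells and at 195 CPM, 1209 reads, in ARL11 cells. ARL11 was therefore 307-fold higher in ARL11 cells in DMSO when taken against a floor of 3 reads per library, with an exact 95% lower limit of 249, and 439-fold higher in olaparib (149.9 to 2132). Within ARL11 cells its level was 1.58-fold higher in olaparib than in DMSO (1.45 to 1.72). The 4 libraries matched their labels in this gene.

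Of the drug's targets, PARP1 (ENSG00000143799.13, chromosome 1, 226360691 to 226408079) stood at 285 CPM in vector cells and 279 CPM in ARL11 cells in DMSO, and at 201 and 214 CPM in olaparib. PARP1 was 0.705-fold its DMSO level in vector cells (0.658 to 0.755) and 0.767-fold in ARL11 cells (0.717 to 0.821). PARP2 (ENSG00000129484.13, chromosome 14, 20343582 to 20357905) went from 45.5 to 26.2 CPM and from 44.8 to 23.3 CPM, which is 0.575-fold (0.477 to 0.692) and 0.521-fold (0.427 to 0.633). Both fell with olaparib over the 2 lines in limma's additive model with Benjamini-Hochberg adjustment, PARP1 with an adjusted p of 6.97e-04 and PARP2 with 2.41e-04. Between the lines PARP1 differed by less than counting error, at 0.980-fold in DMSO (0.923 to 1.04) and 1.07-fold in olaparib (0.988 to 1.15). The corresponding PARP2 values were 0.985-fold (0.847 to 1.14) and 0.892-fold (0.712 to 1.12).

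The comparison of olaparib with DMSO asks which genes responded to the inhibitor in each line. GDF15, a stress-induced cytokine of the TGF-beta family, was 16.4-fold higher in vector cells (14.1 to 19.3) and 15.04-fold higher in ARL11 cells (13.1 to 17.4). ISG15, an interferon-induced ubiquitin-like modifier, was 8.56-fold (8.23 to 8.90) and 8.77-fold (8.45 to 9.12) higher, and reached 3285 and 3271 CPM. XRCC5, a subunit of the Ku heterodimer that binds broken DNA ends, was 5.98-fold lower in vector cells, from 333 to 55.7 CPM, and 5.22-fold lower in ARL11 cells, from 319 to 61.2 CPM. ATR, the kinase of the replication stress checkpoint, was 5.31-fold and 5.99-fold lower, on 53 and 39 reads in olaparib. All 4 genes passed limma's additive test over the lines, GDF15 with a log2 change of 3.92 (SE 0.106, Benjamini-Hochberg adjusted p of 4.83e-11) and ISG15 with 3.11 (SE 0.0788, adjusted p of 4.21e-11). The limma values were -2.46 for XRCC5 (SE 0.0999, adjusted p of 2.58e-09) and -2.34 for ATR (SE 0.187, adjusted p of 3.76e-07). These genes were chosen from the same libraries for large ratios of the same sign in both lines. Their p-values therefore add no support.

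The other genes named by the preset rule on the higher side were CCL5, KRT17, CST1, HES4, C1QL1, CH25H, CXCL11 and SERPINB2. CCL5 and CXCL11 are chemokines, KRT17 is a keratin of basal epithelium, CST1 is a cysteine protease inhibitor and CH25H makes an oxysterol. KRT17 was 17.8-fold higher in vector cells (10.2 to 33.9) and 13.95-fold in ARL11 cells (8.70 to 23.7), and CST1 was 13.1-fold (10.1 to 17.3) and 9.32-fold higher (7.32 to 12.01). CCL5 went from 0.669 to 16.7 CPM in vector cells and from 0.122 CPM, 1 read, to 15.5 CPM in ARL11 cells. SERPINB2, an inhibitor of plasminogen activators, went from 3 to 50 reads and from 2 to 55 reads. On the lower side stood CEP170, TUT7, SF3B1, CDC42BPA, DNAJC13, PNN, DHX29 and PLCE1. SF3B1, a core splicing factor, was 5.59-fold lower in vector cells and 5.02-fold lower in ARL11 cells, and PNN, a nuclear protein tied to splicing, was 4.99-fold and 5.03-fold lower. CEP170, a centrosomal protein, was 6.86-fold and 6.30-fold lower, on 31 and 32 reads in olaparib. All of these genes passed limma's additive test, with the highest adjusted p at 2.49e-06, for SERPINB2. That too follows from their choice for large ratios of the same sign in both lines.

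Across 12000 genes, 835 were at least 2-fold higher and 2399 at least 2-fold lower with olaparib in vector cells. In ARL11 cells 662 were higher and 1684 lower. Both lines shared 437 higher genes and 1503 lower genes, where independent lists of these sizes would share 46.1 and 337. Log2 ratios of the lines correlated with a Pearson r of 0.91 and a Spearman rho of 0.91 across genes, which are not independent replicates, and the comparisons share no library. Poisson counts simulated without an olaparib effect gave at most 10 genes past 2-fold in vector cells and 9 in ARL11 cells over 100 simulations. In limma's additive model 3643 genes rose and 4340 fell at an adjusted p under 0.05.

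**Figure D1:**
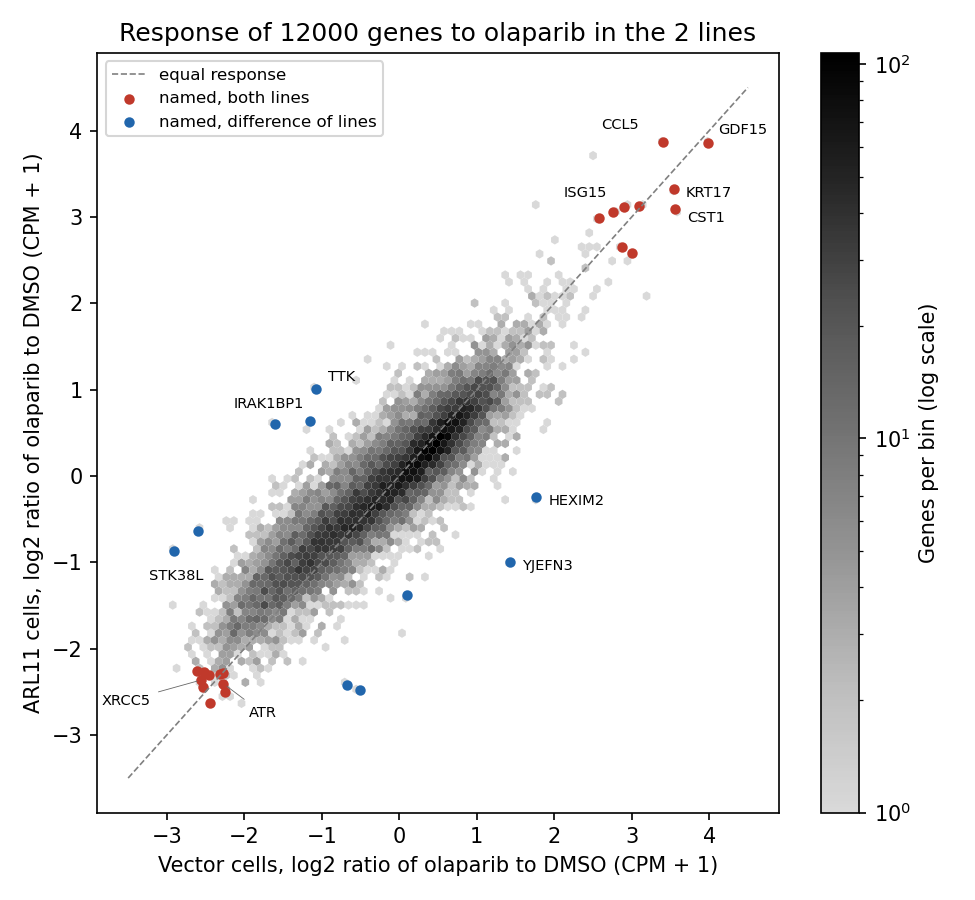
Log2 ratio of olaparib to DMSO (CPM plus 1) in vector cells on the x axis and in ARL11 cells on the y axis, for 12000 genes binned in hexagons shaded by the number of genes on a log scale. Red points are the 20 genes named for the response in both lines, blue points are the 10 genes named for the difference between the lines, and the dashed line marks equal responses. Most genes lie along the dashed line, with GDF15 at 3.98 and 3.86 and XRCC5 at -2.56 and -2.36, while TTK lies at -1.08 and 1.0.

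Response sizes followed the GC content and the length of the transcripts. Over the GC deciles the median log2 ratio in vector cells went from -1.0 in the decile of lowest GC content to 0.69 in the highest, and in ARL11 cells from -0.67 to 0.59. Spearman rho across 11990 genes with GC content was 0.69 in vector cells and 0.59 in ARL11 cells, and with transcript length it was -0.45 and -0.48. Genes at least 2-fold lower in both lines had a median GC content of 41.2% and a median transcript length of 4325 nt. Genes at least 2-fold higher in both had 58.2% and 1509 nt, and all 12000 genes had 48.4% and 2472.5 nt. With a smooth trend in length and GC content removed from each library, a step chosen after seeing the data, 217 genes were higher and 350 lower in both lines. Of the 437 higher genes 117 remained so and of the 1503 lower genes 272 remained so. The genes that rose in limma's additive model then numbered 1850, of which 1188 had risen before, and those that fell 4062, of which 2544 had fallen before. The removal kept each library's mean over genes, and the middle of random lists then lay below 0. The cGAS-STING pathway genes, for example, had a median of -0.17 in vector cells at percentile 53.1. This tilts calls with the trend removed towards falling, here and in the lists below. The 20 genes named above for olaparib shifted without the trend, with log2 ratios in vector and ARL11 cells of 2.84 and 2.93 for GDF15, 1.71 and 1.98 for ISG15, -1.93 and -1.83 for XRCC5, -1.06 and -1.43 for ATR, -2.09 and -2.10 for SF3B1 and 3.15 and 3.36 for SERPINB2. All 20 were still past 2-fold in both lines.

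**Figure D2:**
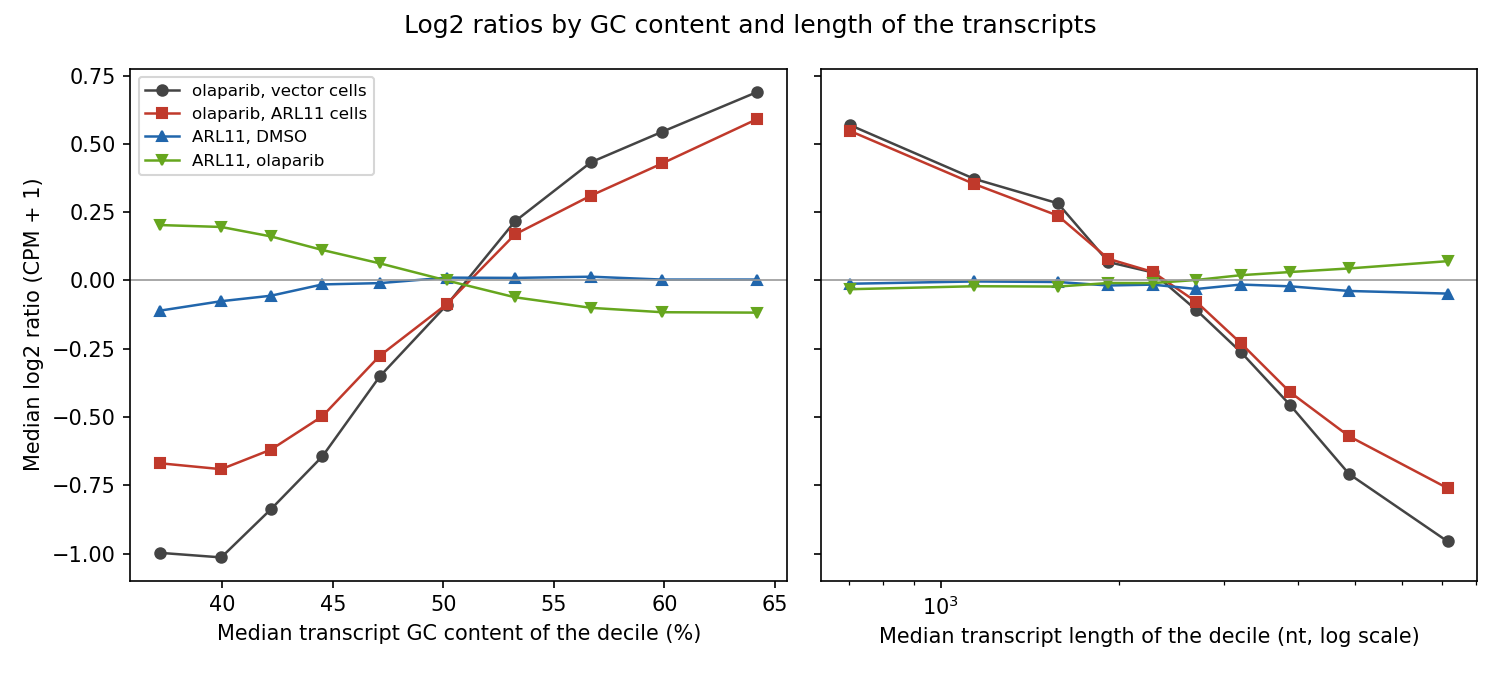
Median log2 ratio (CPM plus 1) of the genes in each decile of transcript GC content on the left and of transcript length in nucleotides, on a log axis, on the right, with 1 line for each of the 4 comparisons. With olaparib the medians climb with GC content from -1.0 to 0.69 in vector cells and from -0.67 to 0.59 in ARL11 cells, and decline with length from 0.57 to -0.96 and from 0.55 to -0.76.

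Interferon-stimulated genes were higher with olaparib in both lines. Their median log2 ratio over 41 measured genes was 0.68 in vector cells and 0.96 in ARL11 cells, at percentile 100 of 10000 random lists of like expression in each. In limma's additive model 27 rose, 5 fell and 9 did not pass, with the same 27 and 5 when adjusted over the list alone. CXCL10, a T cell chemokine, rose by 2.54 in vector cells and 3.71 in ARL11 cells on the log2 scale, while SAMD9, an antiviral factor, was at -1.32 and -1.19. After removal of the trend the medians were 0.63 and 0.79, again at percentile 100, and 26 genes rose and 1 fell in limma's model. Among all genes 1850 then rose and 4062 fell.

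Inflammatory, antigen presentation and immediate early genes were higher as well. Of 24 NF-kB and inflammatory cytokine genes 20 rose and 2 fell in limma's additive model, with medians of 0.99 and 1.021 in vector and ARL11 cells. IL1B, a pyrogenic cytokine, was at 2.36 and 2.38, and NFKB1, a subunit of NF-kB itself, fell with -0.70 and -0.65. Of 17 MHC class I and antigen presentation genes 12 rose and 3 fell, with medians of 0.92 and 0.79. PSMB9, an immunoproteasome subunit, was at 1.68 and 1.53, and ERAP1, a peptide-trimming protease, fell with -1.05 and -1.15. HLA-B, at 1.35 and 1.16, shares sequence with the other class I genes, so its reads are uncertain. Of 19 immediate early genes, the transcription factors and feedback regulators induced first after a stimulus, 14 rose and 2 fell, with medians of 1.11 and 0.86. Adjusted over the list alone, the counts were 20 and 2 for NF-kB, 12 and 4 for MHC class I and 14 and 2 for immediate early genes. All 3 lists were at percentile 100 in both lines. With the trend removed their medians were 0.57 and 0.55, 0.30 and 0.32, and 0.36 and 0.35, at percentile 99.8 or above, and limma's model had 17 rising and 1 falling, 9 and 1, and 9 and 3.

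Of 27 measured p53 target genes 11 rose, 4 fell and 12 did not pass in limma's additive model, and 10 rose and 4 fell when adjusted over the list alone. GDF15 and BBC3, a pro-apoptotic member of the BCL2 family, led the list, with BBC3 at 1.28 in vector cells and 1.78 in ARL11 cells, while RRM2B, a ribonucleotide reductase subunit, fell with -1.21 and -1.0. The list median was 0.14 in each line, at percentiles 82.6 and 85.2. Of 21 genes for cyclins, CDK inhibitors and senescence 12 rose and 6 fell, also adjusted over the list alone, with medians of 0.46 (percentile 96.4) and 0.43 (98.5). CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, was at 1.59 and 1.34, and CDK6 fell with -1.66 and -1.22. Without the trend the p53 medians were 0.06 and 0.07 (percentiles 98.4 and 95.9) and the cyclin medians 0.02 and 0.06 (96.1 and 95.5). Limma's additive model then had 6 rising and 7 falling p53 target genes, and 8 and 7 cyclin genes.

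Ribosomal protein, respiratory chain, histone and lysosomal genes were higher. Of 77 cytosolic ribosomal protein genes 68 rose and 3 fell in limma's additive model, with medians of 0.87 and 0.84 and RPS29 at 1.66 and 1.57. Of 44 nuclear oxidative phosphorylation genes 33 rose and 4 fell, with medians of 0.60 and 0.59, COX5B of the terminal oxidase at 1.43 and 1.23 and UQCRC2 of the bc complex at -1.45 and -1.06. Of 11 measured replication-dependent histone genes 10 rose and none fell, with medians of 1.05 and 0.91 and H2BC11 at 1.64 and 1.60. Histone genes are near-identical copies and their counts are uncertain. Of 38 lysosome and autophagy genes 20 rose and 3 fell, with medians of 0.44 and 0.31 and NEU1, a lysosomal sialidase, at 1.06 and 1.03. Adjusted over the list alone, 34 oxidative phosphorylation genes rose and 4 fell, and the counts for ribosomal proteins, histones and lysosome were again 68 and 3, 10 and 0, and 20 and 3. The percentiles were 97.7 or above in both lines for these 4 lists. The median transcript lengths were 750.5 nt for ribosomal proteins, 805 nt for oxidative phosphorylation and 715.5 nt for histones. With the trend removed the medians were 0.11 and 0.19 for ribosomal proteins, 0.07 and 0.20 for oxidative phosphorylation, 0.96 and 0.86 for histones, and -0.02 and 0.05 for the lysosome. The percentiles were then 98.2 or above, except for the lysosome in vector cells (96.5). In limma's additive model 37 ribosomal protein genes then rose and 21 fell, with 19 and 8 for oxidative phosphorylation, 7 and 1 for histones and 8 and 6 for the lysosome.

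DNA repair genes were lower. Of 43 homologous recombination and Fanconi genes 22 fell, 6 rose and 15 did not pass in limma's additive model, with medians of -0.86 in vector cells and -0.60 in ARL11 cells at percentiles 0.120 and 0.330. RBBP8, an endonuclease cofactor of DNA end resection, was at -2.77 and -1.97, TOPBP1, an activator of ATR, at -2.67 and -2.15, and XRCC3, a recombination factor, at 0.99 and 0.60. Of 21 genes for end joining and control of resection 15 fell, 5 rose and 1 did not pass, with medians of -1.18 and -0.92 at percentiles 0.0200 and 0.05. XRCC5 fell in this list, as did RIF1, a protector of broken ends, at -2.13 and -1.84, whereas MAD2L2, a shieldin subunit, rose with 0.90 and 0.76. Adjusted over the list alone, 22 fell and 6 rose, and 15 fell and 5 rose. The median GC content was 42.8% for homologous recombination and 44.4% for end joining. Without the trend the homologous recombination medians were -0.29 and -0.22 (percentiles 20.3 and 18.95) and the end joining medians -0.50 and -0.45 (1.19 and 0.535). Limma's model then had 16 falling and 3 rising, and 15 and 1. Among all genes 4062 then fell and 1850 rose. Gene span was not part of the removed trend. Its median was 54680 nt for homologous recombination and 57074 nt for end joining, against 30830.5 nt for all 12000 genes. The low end joining medians are therefore not free of an association with gene span.

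Of 44 mitosis genes 23 fell and 11 rose in limma's additive model, also adjusted over the list alone. MKI67, the proliferation marker, was at -2.03 and -1.89, ECT2, an exchange factor of cytokinesis, at -2.17 and -2.01, and MAD2L1, of the spindle checkpoint, rose with 0.90 and 0.84. The list median was -0.55 in vector cells (percentile 0.05) and -0.20 in ARL11 cells (3.89), and -0.29 and -0.24 with the trend removed (9.31 and 5.57). Of 47 S-phase and replication genes 11 rose, 13 fell and 23 did not pass, and 11 rose and 12 fell when adjusted over the list alone. CDT1, a replication licensing factor, was at 1.34 and 1.01 and RRM1, the large subunit of ribonucleotide reductase, at -1.75 and -1.86. The medians were -0.01 and -0.02, at percentiles 42.2 and 42.1, and -0.10 and -0.03 with the trend removed. Limma's model then had 24 falling and 8 rising mitosis genes, and 12 and 8 S-phase genes.

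Heat shock, YAP target, ribosome biogenesis and fatty acid synthesis genes were lower. Of 13 heat shock genes 8 fell and 2 rose in limma's additive model, with medians of -1.0 and -0.39 at percentiles 0.0200 and 1.87. HSP90AA1, the inducible cytosolic chaperone, went from 879.5 to 175 CPM in vector cells and from 762 to 171 CPM in ARL11 cells. Of 24 YAP target genes 15 fell and 3 rose, with medians of -0.75 and -0.82 at percentiles 0.0400 and 0, and TEAD1, the DNA-binding partner of YAP, at -1.93 and -1.66. Of 30 ribosome biogenesis and MYC target genes 15 fell and 4 rose, with medians of -0.52 (0.620) and -0.30 (3.48) and NOP58 of the nucleolar box C/D particles at -2.20 and -1.69. Of 12 fatty acid synthesis genes 8 fell and 2 rose, with medians of -0.64 (1.33) and -0.57 (0.890) and ELOVL6, an elongase, at -1.74 and -1.66. Adjusted over the list alone, these 4 pairs of counts were again 8 and 2, 15 and 3, 15 and 4, and 8 and 2. With the trend removed the medians were -0.74 and -0.45 for heat shock, -0.69 and -0.61 for YAP targets, -0.68 and -0.54 for ribosome biogenesis, and -0.46 and -0.45 for fatty acid synthesis, at percentiles of 2.48 or below. Limma's model then had 11 falling and 0 rising, 18 and 2, 23 and 0, and 10 and 1. Gene span, which the removed trend did not include, had a median of 30830.5 nt over all 12000 genes. It was longer for YAP targets (44386 nt) and fatty acid synthesis (64574.5 nt), and shorter for heat shock (15001 nt) and ribosome biogenesis (15799.5 nt).

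Of the 15 mitochondrially encoded genes 11 fell and 1 rose in limma's additive model, also adjusted over the list alone. MT-RNR2, the large mitochondrial ribosomal RNA, was at -1.14 and -1.18, MT-ND3 of complex I rose with 0.87 and 0.69, and MT-CYB was at 0.19 and -0.12. The median was -0.26 in vector cells (percentile 2) and -0.46 in ARL11 cells (0.225), and -0.31 and -0.48 with the trend removed (15.6 and 0.270), where 12 fell and 1 rose in limma's model.

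**Figure D3:**
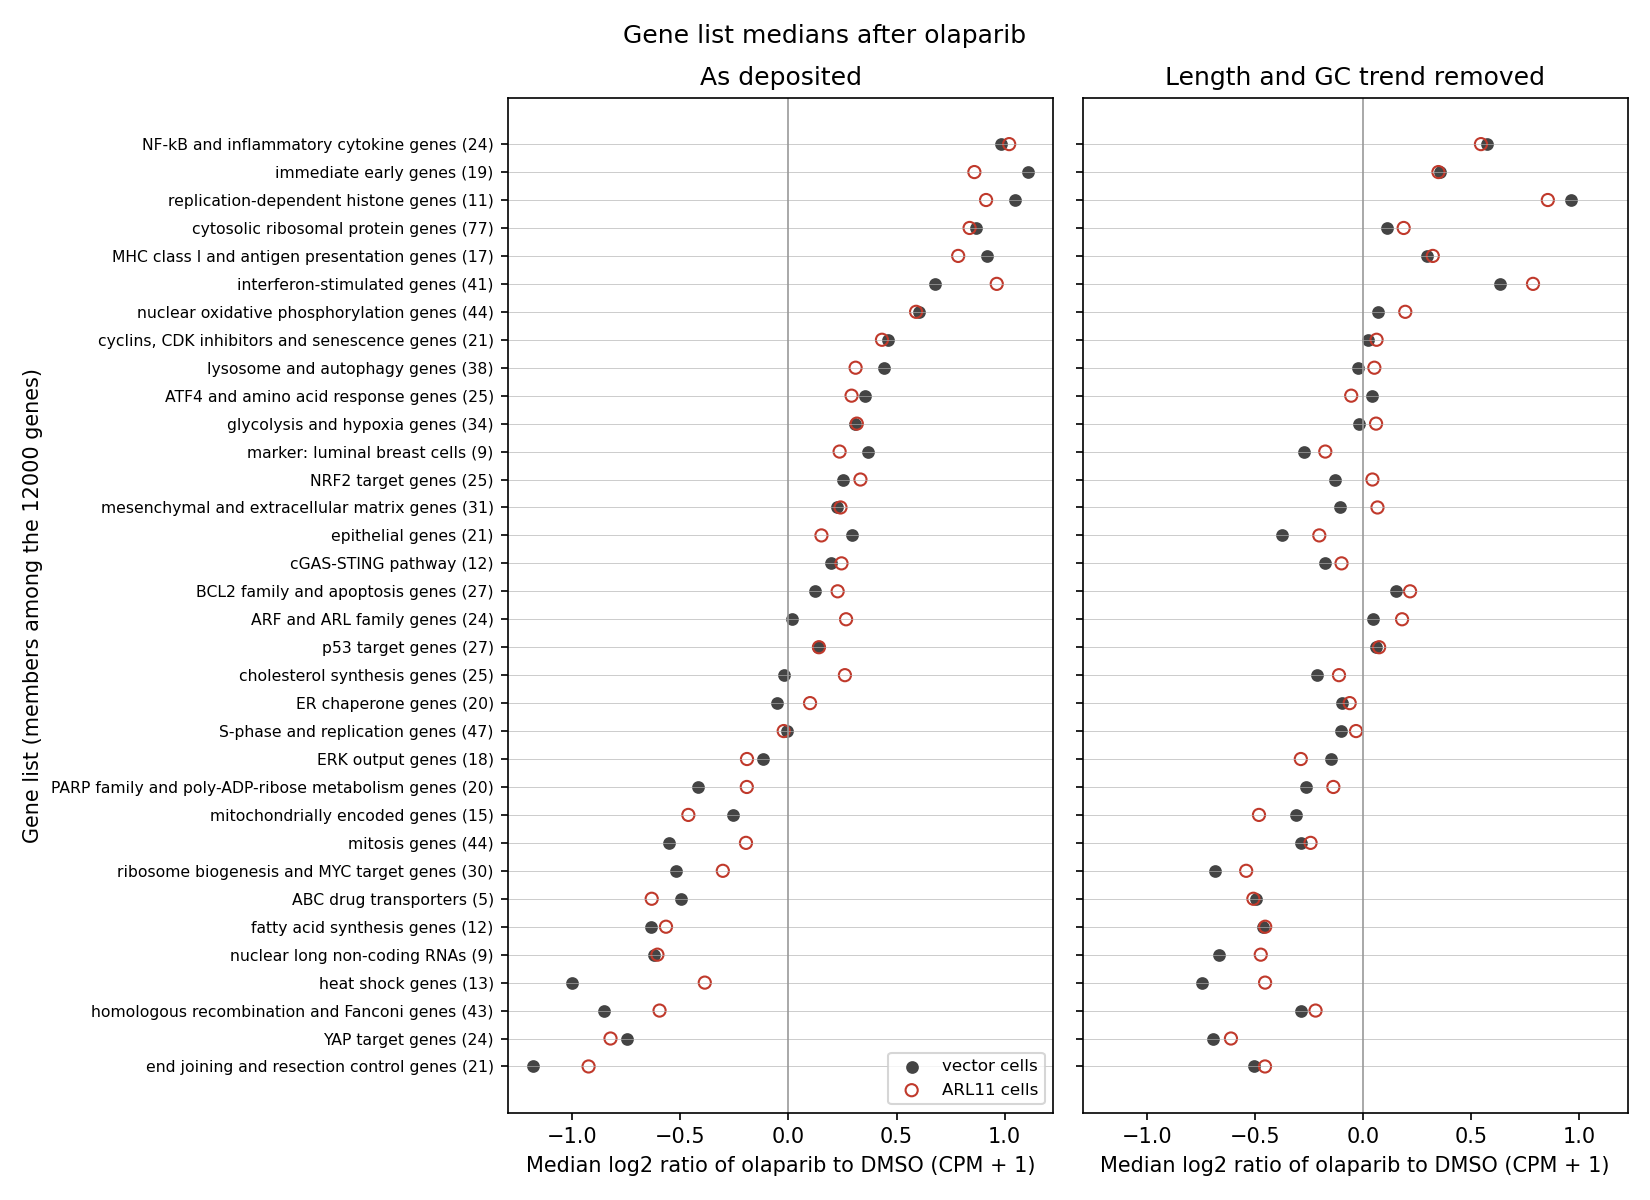
Median log2 ratio of olaparib to DMSO (CPM plus 1) for the 34 gene lists with at least 5 measured members, given in brackets, with filled points for vector cells and open points for ARL11 cells. The left panel shows the values as deposited and the right panel those with the length and GC trend removed. Interferon-stimulated genes lie at 0.68 and 0.96 on the left and 0.63 and 0.79 on the right, and homologous recombination and Fanconi genes at -0.86 and -0.60 on the left and -0.29 and -0.22 on the right.

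The comparison of ARL11 cells with vector cells asks what ARL11 overexpression changed without the drug and with it. Few genes differed. In DMSO 17 genes were at least 2-fold higher and 9 lower, where Poisson counts alone gave at most 7 in either direction over 100 simulations. In olaparib 49 were higher and 13 lower, against at most 15. With a pseudocount of 5 in place of 1, ARL11 alone was past 2-fold in DMSO and 3 genes were in olaparib, namely ARL11, TTK and STK38L. By CPM plus 1, ARL11 was the 1 gene past 2-fold under both treatments, and by the ratio of CPM AXIN2 was as well, on the lower side. In limma's additive model ARL11 rose (7.02, adjusted p of 2.56e-10) and no gene fell. At an unadjusted p under 0.05 limma gave 169 higher and 172 lower among the other 11999 genes, where about 600.0 would be reached by chance. Such a shortfall can arise where the departure from additivity, which is the error of this test, is large. It is no evidence that ARL11 had no effect. The simulated counts held no ARL11 change, so the power to find one is not known. At an adjusted p under 0.05 edgeR and DESeq2 each called ARL11 itself higher and 0 genes lower. Across genes other than ARL11 the log2 ratios under the 2 treatments correlated with an r of -0.05 and a rho of -0.07.

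AXIN2, a negative regulator of Wnt signalling, led the genes that the preset rule named as lower in ARL11 cells under both treatments. It stood at 5.75 CPM in vector and 2.56 CPM in ARL11 cells in DMSO and at 5.76 and 2.41 CPM in olaparib, which is 0.446-fold (0.251 to 0.767) and 0.419-fold (0.215 to 0.777). DFFB, the nuclease of apoptotic DNA fragmentation, was at 0.533-fold (0.348 to 0.808) and 0.545-fold (0.297 to 0.969). RN7SL1, the RNA of the signal recognition particle, was at 0.631-fold (0.555 to 0.716) and 0.632-fold (0.554 to 0.719), with limma's adjusted p at 0.398. RN7SL1 and the named pseudogenes RN7SL4P and CHCHD2P9 share reads with near copies and are uncertain. The other named genes on the lower side were GRB7, PTCD1, RBAK, SYDE2 and MGAT5B. On the higher side stood PCDHB9, ZC3H11B, ZNF33B, ZNF821, NINJ2-AS1, SPANXB1, SIAH1, RPL12P12, ATG4A and RNF224. SIAH1, a ubiquitin ligase, was at 1.63-fold (1.16 to 2.30) and 2.04-fold (1.30 to 3.26), and ATG4A, a protease of autophagy, at 1.64-fold (1.21 to 2.26) and 1.67-fold (1.016 to 2.80). PCDHB9, ZC3H11B, SPANXB1 and RPL12P12 have close paralogs or parent genes and are uncertain too, as is the antisense gene NINJ2-AS1, since the use of strand in the counting is not given in the sources used here. None of these 20 genes passed limma's additive test, with adjusted p of 0.398 for RN7SL1 and 0.999 for the rest. Their intervals come from the same reads by which the genes were picked and add no support.

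Gene lists differed little between the lines in DMSO. Of the 34 lists 5 stood apart, where 1.70 random lists would on average, and 2 did when the random lists were not matched on expression. S-phase and replication genes were at a median of 0.05 (percentile 99.7), immediate early genes at 0.09 (99.5) with NR4A3 at 0.94, and MHC class I genes at 0.07 (98.4) with HLA-B at 0.30. The 5 measured ABC drug transporters, which export drugs from cells, were at -0.18 (0.855) with ABCC1 at -0.18, and mitochondrially encoded genes at -0.05 (1.63). Adjusted over all genes, no member of these lists passed limma's additive test for ARL11. Adjusted over the list alone, 2 mitochondrially encoded genes did on the lower side, MT-ND5 at -0.26 and MT-ND6 at -0.27, each with an adjusted p of 0.0497 in limma, named after their values were seen. After removal of the length and GC trend the percentiles in DMSO were 99.4 for S-phase, 98.8 for immediate early, 95.9 for MHC class I, 0.530 for ABC transporter and 16.9 for mitochondrially encoded genes, and oxidative phosphorylation genes came to stand apart (0.340). In olaparib 6 lists stood apart. Interferon-stimulated genes were higher in ARL11 cells at 0.17 (99.9), mitosis genes at 0.11 (99.99), ER chaperones at 0.17 (99.9) and heat shock genes at 0.19 (99.9). Mitochondrially encoded genes were lower at -0.30 (0) and histone genes at -0.19 (1.74). Log2 ratios of ARL11 to vector in olaparib ran against GC content, with a rho of -0.46, and in DMSO the rho was 0.17. With the trend removed, percentiles in olaparib were 99.4 for interferon-stimulated, 95.5 for mitosis, 95.5 for ER chaperone, 99.9 for heat shock, 0 for mitochondrially encoded and 7.41 for histone genes. Ribosome biogenesis genes (99.8), ABC transporters (1.11) and ARF and ARL genes (1.63) then stood apart as well.

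The final comparison asks whether ARL11 cells responded to olaparib differently from vector cells. TTK, a kinase of the spindle checkpoint, was at 43.9 CPM in DMSO and 20.2 CPM in olaparib in vector cells, and at 26 and 53.1 CPM in ARL11 cells. STK38L, a kinase of the Hippo pathway, was 32.0 and 3.40 CPM in vector cells and 30.5 and 16.3 CPM in ARL11 cells. The differences of the log2 responses were 2.08 with a counting error of 0.187 for TTK and 2.04 with 0.297 for STK38L, both on the scale of CPM plus 1. IRAK1BP1 at 2.20 (0.474), SAMD12 at 1.96 (0.412) and ZSCAN16 at 1.78 (0.4497) were the other genes named as higher. On the lower side YJEFN3 was at -2.42 (0.458), HEXIM2, an inhibitor of the elongation factor P-TEFb, at -2.01 (0.417), CEP85L at -1.97 (0.437), GPR135 at -1.74 (0.465) and the pseudogene HNRNPKP2, whose reads are uncertain, at -1.48 (0.4802). All of these genes were picked from the same libraries for the largest differences, so their sizes against counting error add no support.

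In all, the response was higher by at least 1 in ARL11 cells for 175 genes and lower for 65. Poisson counts around an additive response gave at most 54 such genes in either direction over 100 simulations, against 240 observed. With the length and GC trend removed the numbers were 105 and 61, where the simulations treated alike again gave at most 54 in all, and with a pseudocount of 5 they were 19 and, for HEXIM2 and YJEFN3, 2. The design leaves no error for this difference, so it was not tested per gene. Among the lists, interferon-stimulated genes responded more strongly in ARL11 cells by a median of 0.22 (percentile 99.9), with CXCL10 at 1.16, IFIT1, an antiviral protein, at 0.78, and DHX58 at -0.52. Mitosis genes were at 0.16 (99.95), with HMMR at 1.26, ER chaperones at 0.18 (99.8), with HSP90B1 at 0.64, and heat shock genes at 0.18 (99.7), with DNAJA1 at 0.64. Mitochondrially encoded genes were at -0.26 (0), with MT-ND1 at -0.41. The difference ran against GC content with a rho of -0.45. After removal of this trend the medians were 0.16, 0.12, 0.15, 0.19 and -0.29 in the same order of lists, at percentiles of 98.2 or above and, for the mitochondrially encoded genes, 0.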

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

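The simulation of counting error and the removal of the length and GC trend were chosen only after the results were seen.

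Responses to olaparib of opposite sign in the lines marked 6 genes. The differences, ARL11 cells minus vector cells on the log2 scale, were 2.20 for IRAK1BP1, 2.08 for TTK, 1.78 for ZSCAN16, -2.42 for YJEFN3, -2.01 for HEXIM2 and -1.48 for HNRNPKP2. They were not tested, since each group has 1 library. TTK had 328, 213, 137 and 330 reads in vector cells in DMSO, ARL11 cells in DMSO, vector cells in olaparib and ARL11 cells in olaparib. IRAK1BP1 had 32, 19, 5 and 25 reads, ZSCAN16 36, 26, 11 and 34, YJEFN3 15, 37, 48 and 11, HEXIM2 11, 53, 50 and 33, and the pseudogene HNRNPKP2 19, 44, 19 and 9. For 3 of them the 95% interval of 1 line included no change, so opposite signs are not shown for these. They were IRAK1BP1 in ARL11 cells at 1.74-fold (0.918 to 3.33), HEXIM2 in ARL11 cells at 0.821-fold (0.515 to 1.29) and HNRNPKP2 in vector cells at 1.10-fold (0.553 to 2.20). For ZSCAN16 in ARL11 cells the lower limit was 1.005. All 6 genes were picked from these same reads for large differences, so the intervals of the others do not show opposite signs either.

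These genes were the far end of a wider difference, with 240 genes whose responses differed by at least 1, where simulations of counting error gave at most 54. With the length and GC trend removed 166 genes were past that size, and simulations treated alike again gave at most 54. The 240 genes argue against counting error as the whole source, and the 166 against the fitted trend together with counting error. Separate dishes and libraries also vary by more than counting error, and 1 library per group gives no measure of that spread. For genes past that size with the trend removed, ARL11 and other differences between single dishes and libraries cannot be told apart. For the other genes the trend cannot be told apart from these either. An effect of ARL11 on part of the olaparib response may be present, as an untested hypothesis.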

How the results depend on the processing

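The removal of the length and GC trend, with either transcript length, was chosen only after the results were seen. The additive model already compares the treatments within each line. No library could be left out because each group has 1. For each value that moved the cause was not tested, except that fewer genes enter with 8000 genes and more with no filter, and that a pseudocount shifts low genes by construction. In the following, pairs of counts are higher and lower genes.

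With a pseudocount of 5 the olaparib counts were 435 higher in vector cells, 325 and 1101 in ARL11 cells and 226 higher in both, with an r of 0.93. ARL11 against vector gave 1 and 0 in DMSO and 3 and 0 in olaparib, the difference of responses 19 and 2, and the r under both treatments -0.077. The ARL11 gene itself was at 4.68 in DMSO and 5.20 in olaparib. With a pseudocount of 0.1 ARL11 against vector gave 42 and 41 in DMSO and 123 and 44 in olaparib, with 1 gene lower in both, AXIN2. The difference gave 321 and 136, the olaparib r was 0.90, and the ARL11 gene was at 10.27 and 8.49.

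With 8000 genes the counts were 461 and 1580 for olaparib in vector cells, 355 higher in ARL11 cells and 259 higher in both, with an r of 0.95. ARL11 against vector gave 1 and 0 in DMSO and 10 and 1 in olaparib, the 1 being ALKBH2, with an r of -0.13. The difference gave 35 and 2, the latter SLC25A42 and ALKBH2. With no filter ARL11 against vector gave 58 and 54 in DMSO, 151 and 109 in olaparib and 2 and 1 in both, ARL11 with AIM2 and, lower, AC090505.1. The difference gave 539 and 383, and the r was 0.78 for olaparib and -0.023 for ARL11. Limma's additive model for ARL11 then called 2 and 1, as it did when rescaled to the median ratio. In both settings these were ARL11, STK38L and, lower, RN7SL1. These small sets were named after their values were seen.

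With the trend removed olaparib gave 353 and 788 in vector cells, 363 and 562 in ARL11 cells and 217 and 350 in both, with an r of 0.82. ARL11 gave 31 higher in olaparib, an r of 0.013, and 105 higher differences. Limma's additive model called 1850 genes higher with olaparib. The lysosome and autophagy median in vector cells went to -0.024, still high among random lists (percentile 96.5). With the longest transcript the values were 378 and 804, 354 and 569, 226 and 363 with an r of 0.83, then 30, 0.011, 105 and 1874, and -0.061 for the lysosome. Random lists without matching left 2 lists apart for ARL11 in DMSO.

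Among summaries, 183 values stayed within 1.5 times or within their interval and 73 moved. Of 1530 list medians 1459 stayed within their interval, 69 moved out of it and 2, for the lysosome, changed sign in a list that had stood apart. Over all lists 142 of the 1530 differed in sign, 45 of them with the trend removed and 47 with the longest transcript. With the trend removed a changed sign need not be a change of direction, since the middle of random lists then lay below 0 for olaparib. Of named genes 644 values stayed within counting error, 108 moved and 0 changed sign. Those that moved were 33 with the trend removed, 35 with the longest transcript, 30 and 8 with pseudocounts of 5 and 0.1 and 2 with the upper quartile. Of those that stayed, 32 with 8000 genes and 90 with no filter could not move. A gene's ratio does not depend on which other genes are kept. Named genes were also chosen for large values, so few changes of sign could arise. Depth limits the named ARL11 genes and the differences, of which many have under 50 reads in at least 1 library.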

Other observations

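The removal of the length and GC trend, the partial rank correlations and the simulation of counting error for the genes lower in both lines were chosen only after the results were seen.

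Other gene groups held members that went both ways with olaparib. Of 12 measured cGAS-STING pathway genes 6 rose and 4 fell in limma's additive model, also adjusted over the list alone. IFNL1, a type III interferon, was at 1.95 in vector cells and 2.47 in ARL11 cells, and IFI16, a DNA sensor, at -1.99 and -2.37. The medians were 0.20 and 0.25, at percentiles 73.4 and 85.1. Of 25 ATF4 and amino acid response genes 12 rose and 7 fell, 13 and 7 adjusted over the list alone, with DDIT4, an inhibitor of mTOR signalling, at 1.70 and 1.71 and SLC7A11, the cystine transporter, at -1.54 and -0.84. The medians were 0.35 and 0.29 (93.8 and 93.8). Of 27 BCL2 family and apoptosis genes 12 rose and 6 fell, also adjusted over the list alone, with PMAIP1, a pro-apoptotic BH3 protein, at 1.36 and 1.56 and BIRC2, an inhibitor of apoptosis, at -2.42 and -1.93. Their medians were 0.12 and 0.23 (75.4 and 92.4). Of 20 genes of the PARP family and poly-ADP-ribose metabolism 5 rose and 9 fell, also adjusted over the list alone. PARP10 was at 1.19 and 1.24 and PARG, the glycohydrolase that degrades poly-ADP-ribose, at -1.78 and -1.07. The medians were -0.42 and -0.19 (16.5 and 31.0). After removal of the trend limma's additive model had 4 rising and 3 falling for cGAS-STING, 5 and 9 for ATF4, 9 and 5 for BCL2 and 6 and 8 for the PARP family. The medians were then -0.17 and -0.10, 0.04 and -0.05, 0.15 and 0.22, and -0.26 and -0.14 in the same order of lists. BCL2 genes then stood apart in both lines (both 99.9) and ATF4 genes in vector cells (97.8).

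Of 34 glycolysis and hypoxia genes 18 rose and 7 fell in limma's additive model, with VEGFA at 1.48 and 1.53 and medians of 0.31 and 0.32. NRF2 targets had 11 rising and 6 falling of 25, with FTH1 of the iron store ferritin at 1.14 and 0.87 and medians of 0.25 and 0.33. Cholesterol synthesis had 10 and 7 of 25, with HMGCS1 at -1.40 and -0.80 and medians of -0.02 and 0.26. ER chaperones had 9 and 7 of 20, with DNAJC3 at -1.79 and -1.28 and medians of -0.05 and 0.10. Mesenchymal and matrix genes had 15 and 9 of 31, with ZEB1 at -1.92 and -1.76 and medians of 0.23 and 0.24. Epithelial genes had 10 and 5 of 21, with TJP1 of tight junctions at -2.63 and -1.76 and medians of 0.29 and 0.15. Among ERK output genes 4 rose and 8 fell of 18, with DUSP5 at 1.22 and 1.26 and medians of -0.12 and -0.19. In the ARF and ARL family 11 rose and 8 fell of 24, with medians of 0.02 and 0.27. Of 9 measured members of the list of nuclear long non-coding RNAs, called nuclear RNAs below, 7 fell, with medians of -0.62 and -0.61. TUG1 was at -1.69 and -1.74. The list also holds GAS5, SNHG1, SNHG5 and SNHG12, and where its RNAs lie in the cell was not examined. GAS5 (0.05 and 0.35) and SNHG12 (-0.23 and 0.29) were the 2 that did not pass. Of 5 ABC drug transporters 3 fell, with ABCC4 at -2.02 and -1.70 and medians of -0.50 and -0.63. Adjusted over the list alone, the ER chaperones had 9 rising and 8 falling, and the other counts of this paragraph did not move. None of these lists stood apart with olaparib in either line. After removal of the trend limma's additive model had 12 rising and 9 falling for glycolysis, 5 and 7 for NRF2, 3 and 6 for cholesterol, 3 and 7 for ER chaperones and 10 and 10 for mesenchymal genes. Epithelial genes then had 3 and 9, with medians of -0.37 and -0.20. That turned the sign in both lines, and it also turned in vector cells for mesenchymal (-0.10), NRF2 (-0.13) and glycolysis genes (-0.019) and in ARL11 cells for cholesterol (-0.11) and ER chaperone genes (-0.061). Of these, only epithelial genes also went to the lower side of random lists, at percentiles 7.25 and 24. The others lay above the middle, at 76.7, 68.25, 96.4, 57.0 and 67.6 in the same order of lists. Their signs are thus no change of direction, since the removal kept each library's mean over genes and 0 was not the middle. The counts were 5 and 9 for ERK, 8 and 6 for ARF and ARL, 1 and 6 for nuclear RNAs and 0 and 4 for transporters. Lists that then stood apart in a line were glycolysis (97.9) and mesenchymal genes (98.0) in ARL11 cells, and in both lines ARF and ARL (97.9 and 99.8) and nuclear RNAs (0.420 and 2.23). The 1 measured MHC class II gene, CD74, was at 1.19 and 0.83.

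Markers of other cell types were looked up too. Of blood and immune markers 13 were listed and 0 lay among the 12000 genes, with CSF1R the highest at 2.51 CPM. Of neural and embryonic kidney line markers 5 were listed and 0 lay there, with MAP2 the highest at 3.70 CPM. Of fibroblast and endothelial markers 4 did, with COL1A1 the highest at 14.7 CPM, and PECAM1 at 1.06 and 0.93 with olaparib. Of luminal breast markers 9 did, with KRT8 at up to 615 CPM, and 6 rose and 1 fell in limma's additive model, with medians of 0.37 and 0.24. After removal of the trend 0 rose and 4 fell, with medians of -0.27 and -0.17 (percentiles 30.4 and 35.2).

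Genes at least 2-fold lower with olaparib in both lines were long and poor in GC. With the trend removed 272 stayed so and simulations of counting error gave 0, which argues against counting error as the whole source. Single dishes and libraries vary by more than counting error, so the source is otherwise left open. Each property went with the response at like values of the others, with partial rank correlations, the smaller of the lines, of -0.34 for transcript length, -0.22 for gene span and 0.53 for GC content. A length and GC trend as the whole source was left undecided, since 18.1% of the genes stayed lower. That lies between bounds set before this share was computed, though after the data had been seen. The removal kept each library's mean over genes, which makes it easier for a gene to stay lower. For the genes that did not stay lower, the trend and olaparib cannot be told apart. Such a trend could come from RNA quality or library preparation or from a loss of long transcripts in the cells, and 1 library per group leaves these open.

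Interferon-stimulated genes were higher with olaparib in both lines. The length and GC trend as the whole source is argued against, since with the trend removed the list's median lay at percentile 100 in both lines. An interferon response to olaparib is a hypothesis in line with this test, and was not tested apart from differences between single libraries.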
